A study of Sus scrofa with 16 samples.

How the data were processed

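Total RNA from liver of 16 pigs was labelled with Cy3 and hybridised to 1-channel Agilent porcine arrays, 1 array per pig, with 8 low-RFI and 8 high-RFI pigs. Per the file headers, the scans were read with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09. Per the file headers, the processed signal of each spot is an intensity on a linear scale, background-subtracted and detrended within its array but not normalised between arrays. The mean spot signal and the median local background are also intensities per the file headers. The deposited series table by the authors holds log2 values of 27938 spots. Each of its 16 columns equalled the log2 processed signal of its own array minus the median over the listed spots, with a largest difference of 4.5e-08. The rule by which the authors kept spots is not given in the sources used here. The listed spots were well above background on at least 10 arrays, and 413 spots that were well above background on all 16 arrays were not listed. The submitters' processing notes name R 2.10.0.

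Levels were computed from the processed signal of the scanner files. Spots that the scanner software marked as outliers were set to missing, the 75th percentile of log2 signal was subtracted from each array, and spots of the same probe were averaged. Of 43603 probes on the array, 30097 were tested, namely those well above background on at least 8 of the 16 arrays, and 13506 were left out as too dim. Probes were named from the files and from tables that pair RefSeq accessions and gene numbers with symbols. Of 5779 probes with a RefSeq accession as their name, 5461 were matched there. In all, 12167 probes carried exactly 1 symbol, for 5362 symbols, and 31436 carried none or several. No genome sequence was used, so probe positions are not given. A gene was represented by its tested probe with the highest mean level, which gave 4513 genes.

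The comparison was low-RFI minus high-RFI, fitted with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. Levels are given as means with their SD, changes with their standard error (SE). Gene lists were tested with camera at a preset correlation of 0.01 against all other named genes. Of 34 lists, 31 had at least 5 tested members. Camera with a correlation estimated from the data and fry were alternatives, and fry tests only whether a list's genes move on balance in 1 direction. The 10 missing values of the represented genes were filled for these tests. Array quality was compared by exact two-sided permutation tests over all 12870 splits of the arrays. Relations between list means over the 16 pigs were tested two-sided with 100000 permutations. Data handling used jsonlite 2.0.0 and the R package for data tables (data.table, version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

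The comparison, its threshold, the filter, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The lists cover fatty acid and triglyceride synthesis, fatty acid oxidation, cholesterol synthesis, bile acids, lipoproteins, gluconeogenesis, glycolysis, amino acid catabolism, the respiratory chain, ribosomal proteins and the proteasome. They also cover endoplasmic reticulum stress, heat shock proteins, antioxidant enzymes, drug and steroid metabolism, acute phase response, complement and coagulation, interferon response, MHC, growth hormone and insulin signalling, the circadian clock and the cell cycle. Marker lists cover hepatocytes, pericentral hepatocytes, T and NK cells, B and plasma cells, Kupffer cells, granulocytes, erythroid cells, stellate cells, endothelium, bile duct, tissue taken along (pancreas, fat and muscle), and Y-linked genes with XIST. Named genes were to be the called genes with the largest change, up to 12 per direction, with up to 3 called members of each called list and 2 of any other list. Had these parts named fewer than 10 genes, the member with the smallest p of each list would have been added. Where a called list had no called member, the 2 members with the smallest p were named, and with fewer than 5 called genes also the 5 genes with the smallest p in each direction.

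The alternatives were normexp background correction with an offset of 50, quantile normalisation, median scaling, cyclic loess and the authors' table. They also included no filter, a filter on all 16 arrays, keeping outlier spots, slide as a fixed or random block, each slide alone, the replicate number as a block, trend with robust variances and array weights. Further ones were other thresholds, means over a gene's probes, the other list tests, and leaving out each pig. After the data had been seen, array position or the series of sample numbers as a block, the first principal component and array noise as covariates, and leaving out the arrays that the scanner software marked for evaluation were added. The analysis was tested on simulated data with 200 changed probes among 30097 and 8 arrays per group. It called 31.3% of probes changed 1.5-fold, 67.2% of those changed 2-fold and 95.5% of those changed 4-fold, with 8 unchanged probes among 137 called. With nothing changed it called 0 probes and 0 lists with limma and camera, and a list of 30 genes shifted by 0.2 on the log2 scale had an adjusted p of 3.79e-09. Each simulated probe was drawn independently of the others. The simulation therefore cannot show how often lists of correlated genes are called when nothing changes. Among its 137 calls a probe passed more easily than among the 3 of the real data, since the Benjamini-Hochberg cut loosens with the number called. Its shares of changed probes called may therefore overstate what the comparison could detect.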

Results

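The data are liver transcript levels of 16 pigs (Sus scrofa) at 20 kg body weight, all fed ad libitum. The pigs belonged to a low-RFI line and a high-RFI line, RFI being residual feed intake, the feed eaten above or below what growth and maintenance predict. There were 8 pigs of each line, and the comparison asks how liver transcript levels differ between these lines after selection on RFI. With no further lines sampled, an effect of selection cannot be told apart from other differences between the lines. Levels are log2 signal relative to the 75th percentile of each array, and changes are low-RFI minus high-RFI. The arrays sat on 4 slides, each with 2 low-RFI and 2 high-RFI pigs. Per array, 28695 to 35126 probes were well above background, the 75th percentile of signal was 320.0 to 508 intensity units, and the median local background was 29 to 40. The number of arrays limits the precision, with a median SE of 0.16 on the log2 scale.

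In low-RFI liver 3 probes fell, none of which carries a gene symbol. A_72_P302174, described in the files as matching human C6orf125, was 2.49-fold lower, at −3.86 ± 0.22 in low-RFI against −2.55 ± 0.37 in high-RFI liver (SD, n = 8 each). C6orf125 is also known as UQCC2, an assembly factor of respiratory complex III. The other 4 probes of this gene, listed as C7H6orf125, had changes of +0.12 to +0.18 with an adjusted p of 0.979 each. Their mean levels, 3.79 to 4.04 in low-RFI and 3.63 to 3.91 in high-RFI liver, were far above that of A_72_P302174. A_72_P205617, described as a liver cDNA clone, was 20.8-fold lower, at −3.25 ± 1.43 against 1.13 ± 1.09 (SD, n = 8 each). A_72_P129381, of unknown identity, was 3.47-fold lower, at −5.04 ± 0.52 against −3.24 ± 0.64 (SD, n = 8 each). The last 2 were well above background in 7 low-RFI and 8 high-RFI pigs, so their folds are not exact. Their 60-base sequences are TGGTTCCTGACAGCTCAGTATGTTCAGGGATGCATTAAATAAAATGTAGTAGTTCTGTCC for A_72_P302174, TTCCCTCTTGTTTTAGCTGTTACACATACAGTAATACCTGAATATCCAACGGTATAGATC for A_72_P205617 and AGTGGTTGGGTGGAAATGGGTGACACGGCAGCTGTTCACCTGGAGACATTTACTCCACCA for A_72_P129381.

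The limma change of A_72_P302174 was −1.32 (SE 0.152, adjusted p = 0.00308). For A_72_P205617 it was −4.38 (SE 0.575, adjusted p = 0.00929) and for A_72_P129381 −1.79 (SE 0.27, adjusted p = 0.0365). For each of the 3 probes, 8 of 8 low-RFI pigs lay below the high-RFI mean. Within slides 1 to 4 the changes were −1.38, −1.41, −0.95 and −1.53 for A_72_P302174. They were −3.39, −4.61, −4.84 and −4.68 for A_72_P205617, and −1.41, −2.31, −1.55 and −1.92 for A_72_P129381. Of 30097 probes tested, 0 rose at an adjusted p under 0.05 in limma, and 751 were higher and 891 lower at an unadjusted p under 0.05, where 1505 in all would be by chance and 28 of 100 splits of the pigs gave as many, or 5 of 100 with slide and series of sample numbers held even. The 2 lines did not overlap in 13 probes, 8 of them lower and 5 higher in low-RFI liver, against 4.68 by chance. Arrays of high-RFI pigs were noisier, with a median coefficient of variation of replicated probes of 8.04 ± 0.66% against 6.97 ± 0.50% (exact permutation p = 0.00373). With this noise as a covariate the changes of A_72_P302174, A_72_P205617 and A_72_P129381 were −1.27, −4.78 and −1.77, and none passed (adjusted p = 0.245, 0.245 and 0.455, over all alternatives 0.00161 to 1, 0.00218 to 1 and 0.0306 to 1). Under normexp, A_72_P302174 was at −0.37 and A_72_P129381 at −0.36 (adjusted p = 0.692 each) and A_72_P205617 passed at a smaller −3.00 (0.00218). The offset of 50 intensity units added there shrinks changes of dim probes whatever their cause. The smaller normexp changes alone therefore cannot decide whether these differences hold. A_72_P129381 did not pass in 15 of 21 settings, among them quantile normalisation (0.0691), cyclic loess (0.0637), no filter (0.0625) and slide as a block (0.123).

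**Figure D1:**
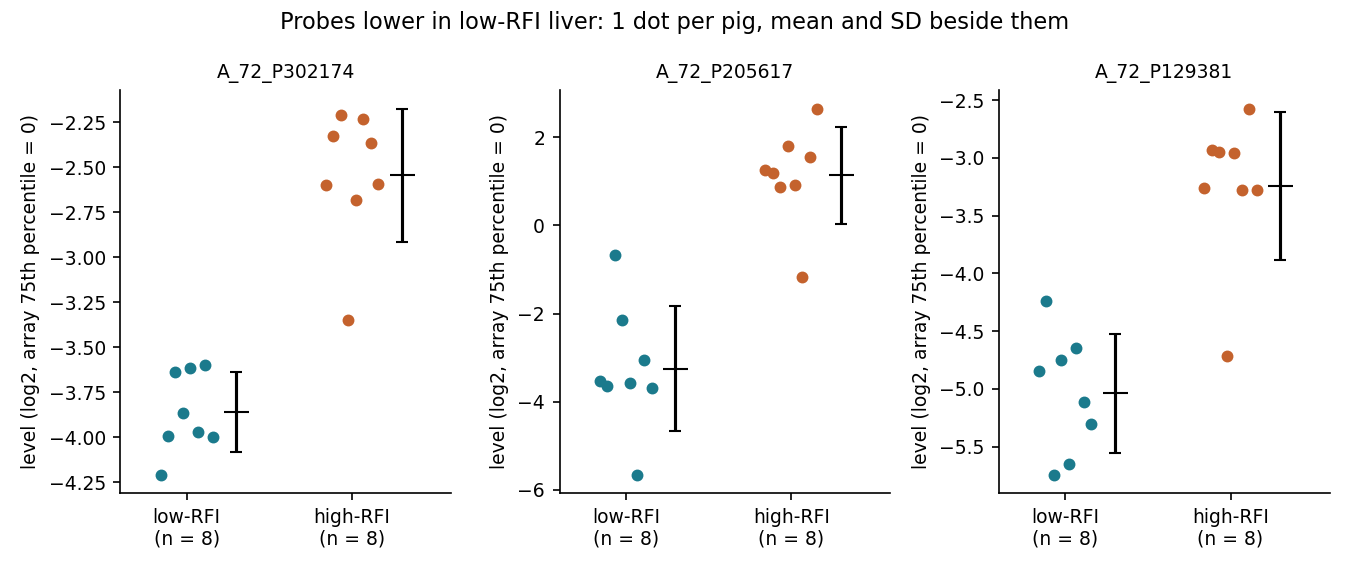
Level of the 3 probes that passed the test in each pig (vertical axis, log2 relative to the 75th percentile of the array; 1 dot per pig; bar, mean and SD; n = 8 per line). Most high-RFI pigs lie above all low-RFI pigs, and only A_72_P302174 shows no overlap.

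No single gene passed the test, so the genes with the smallest p are given as values. TLR5, the receptor for bacterial flagellin, was at −1.87 ± 0.46 in low-RFI and −2.86 ± 0.21 in high-RFI liver (SD, n = 8 each), without overlap. Its change was +0.99 (SE 0.173, adjusted p = 0.124). The next on the higher side were SNRNP48 of the minor spliceosome (+0.84, SE 0.164), RTN2, a reticulon (+0.93, SE 0.234), HSD3B1 of steroid hormone synthesis (+0.82, SE 0.214) and the ubiquitin ligase DZIP3 (+0.53, SE 0.138). On the lower side were OAZ3, an antizyme of ornithine decarboxylase (−2.05, SE 0.496), FAM19A3, a secreted protein (−1.86, SE 0.41), and F13A1, the A subunit of clotting factor XIII (−1.04, SE 0.285). P311 (−0.87, SE 0.236) and MTERFD1, a regulator of mitochondrial transcription (−0.32, SE 0.0893), completed them. Adjusted p of these 9 genes ran from 0.19 for SNRNP48 to 0.476 for MTERFD1. FAM19A3 was well above background in 5 low-RFI and 7 high-RFI pigs, so its change is not exact. Changes were smaller under normexp for FAM19A3 (−0.28), SNRNP48 (+0.42), DZIP3 (+0.27), OAZ3 (−1.40) and TLR5 (+0.66). The offset of that setting shrinks a change the more, the dimmer the probe. Separate probes of 1 gene went the same way for P311 (4 probes, −0.72 to −0.87), MTERFD1 (3 probes, −0.32 to −0.48), DZIP3, F13A1, HSD3B1 and OAZ3, while another probe of RTN2 gave −0.28. Within single slides F13A1 was at +0.13 on slide 1 and RTN2 at −0.18 on slide 2.

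Of 4513 genes, 0 were called by limma, and 225 had an unadjusted p under 0.05, 119 higher and 106 lower. All 26 other settings also gave 0 genes. Leaving out low-RFI pig 2 gave 1 gene (HSD3B1, adjusted p = 0.0196), and so did leaving out low-RFI pig 4 (TLR5, adjusted p = 0.0454). Since no gene was called, agreement between the probes of called genes could not be assessed for any of the 2415 genes with several tested probes.

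**Figure D2:**
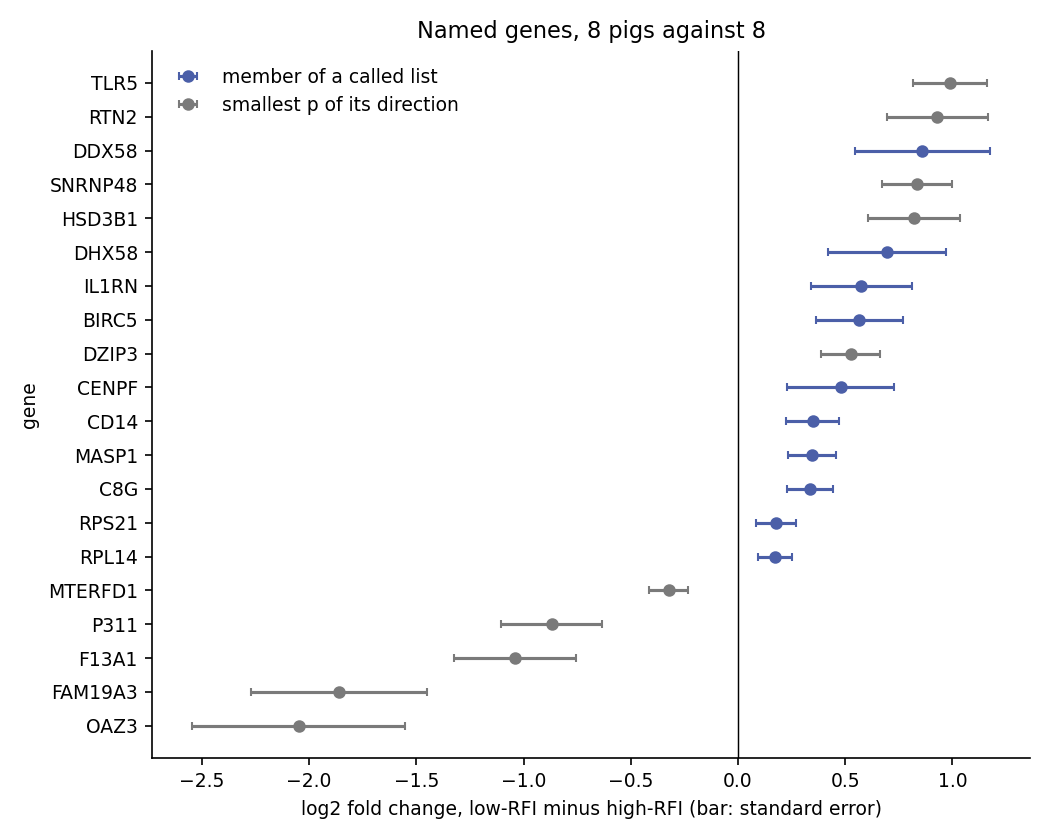
Change of the 20 named genes (horizontal axis, log2, low-RFI minus high-RFI; dot, limma estimate; bar, SE; 8 pigs per line), with members of lists that passed in blue. None passed at the level of single genes, and TLR5 had the smallest p, with a change of +0.99.

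Complement and coagulation genes, which liver secretes for blood defence and clotting, passed as a list on the higher side against all other genes: 28 of 30 were higher in low-RFI liver, with a median change of +0.13 (camera adjusted p = 4.44e-05; adjusted p = 0.974 with an estimated correlation). The median was +0.07 under normexp, where the list did not pass (0.365), and +0.06 under quantile normalisation (0.0222). C8G, the gamma chain of complement C8, was at +0.33 (SE 0.107), with its 3 probes at +0.33 to +0.38. MASP1, a protease of the lectin pathway, was at +0.35 (SE 0.112), but its other probes were at −0.22 and −0.02, and the named probe was at −0.46 within slide 1 and −0.10 within slide 3. Acute phase genes passed as higher as well, with 17 of 22 higher and a median of +0.17 (adjusted p = 0.017; adjusted p = 0.974 with an estimated correlation), but not under normexp (0.212), quantile normalisation (0.221), cyclic loess (0.122) or array weights (0.106). Among them CD14, a co-receptor for endotoxin, was at +0.35 (SE 0.124), and IL1RN, the antagonist of interleukin-1, at +0.58 (SE 0.237) but at −0.41 within slide 4. The second probe of CD14 was at +0.26 (SE 0.177) and that of IL1RN at +0.18 (SE 0.165). Genes of cytosolic ribosomal proteins passed as higher by a small amount, a median of +0.06 with 33 of 40 higher, and the test turned to lower under normexp and quantile normalisation and did not pass under cyclic loess, 0.5 (adjusted p = 0.00661; adjusted p = 0.974 with an estimated correlation). RPL14 was at +0.17 (SE 0.0805) and RPS21 at +0.18 (SE 0.0926).

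The interferon response list passed as higher, with 23 of 30 higher and a median of +0.22 (adjusted p = 0.0137; adjusted p = 0.974 with an estimated correlation). The sensors of viral RNA DDX58 and DHX58 were at +0.86 (SE 0.316) and +0.69 (SE 0.274). The cell cycle list passed as higher, with 13 of 16 higher and a median of +0.34 (adjusted p = 0.0137; adjusted p = 0.974 with an estimated correlation). BIRC5, also called survivin, was at +0.57 (SE 0.202), and CENPF of the kinetochore at +0.48 (SE 0.25). High-RFI arrays were noisier, with a coefficient of variation of 8.04 ± 0.66% against 6.97 ± 0.50%, and with this noise as a covariate the interferon median was +0.27 (adjusted p = 0.273) and the cell cycle median −0.15 (adjusted p = 0.21). Interferon did not pass under normexp (0.113). With array position as a block neither list passed (0.129 for interferon, 0.0749 for cell cycle), nor did either without the marked arrays (0.458, and 0.958 with the cell cycle test turned). None of the members named from the 5 lists passed alone, with adjusted p from 0.622 for C8G to 0.955 for RPS21 and CENPF. Members at an unadjusted p under 0.05 numbered 4 for complement and coagulation, 4 for interferon response, 2 for acute phase, 1 for ribosomal proteins and 1 for cell cycle. Over 25 alternatives adjusted p ran from 4.01e-06 to 0.974 for complement, from 1.72e-05 for acute phase, 6.41e-05 for ribosomal proteins, 7.53e-11 for interferon and 4.3e-05 for cell cycle, with 0.974 the highest for each.

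None of the 5 lists held its call with an estimated correlation, where 0 of 31 lists passed and 0 had an unadjusted p under 0.05, and 0 passed by fry, with 1 at an unadjusted p under 0.05 (complement and coagulation, 0.0244). Within slides 1 to 4, the adjusted p of complement and coagulation was 0.0317, 0.000669, 0.396 and 0.868, and interferon response turned to lower on slide 4 (adjusted p = 9.99e-05), as acute phase did (0.689), while cell cycle turned on slide 2 (0.872) and ribosomal proteins on slide 3 (0.859).

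**Figure D3:**
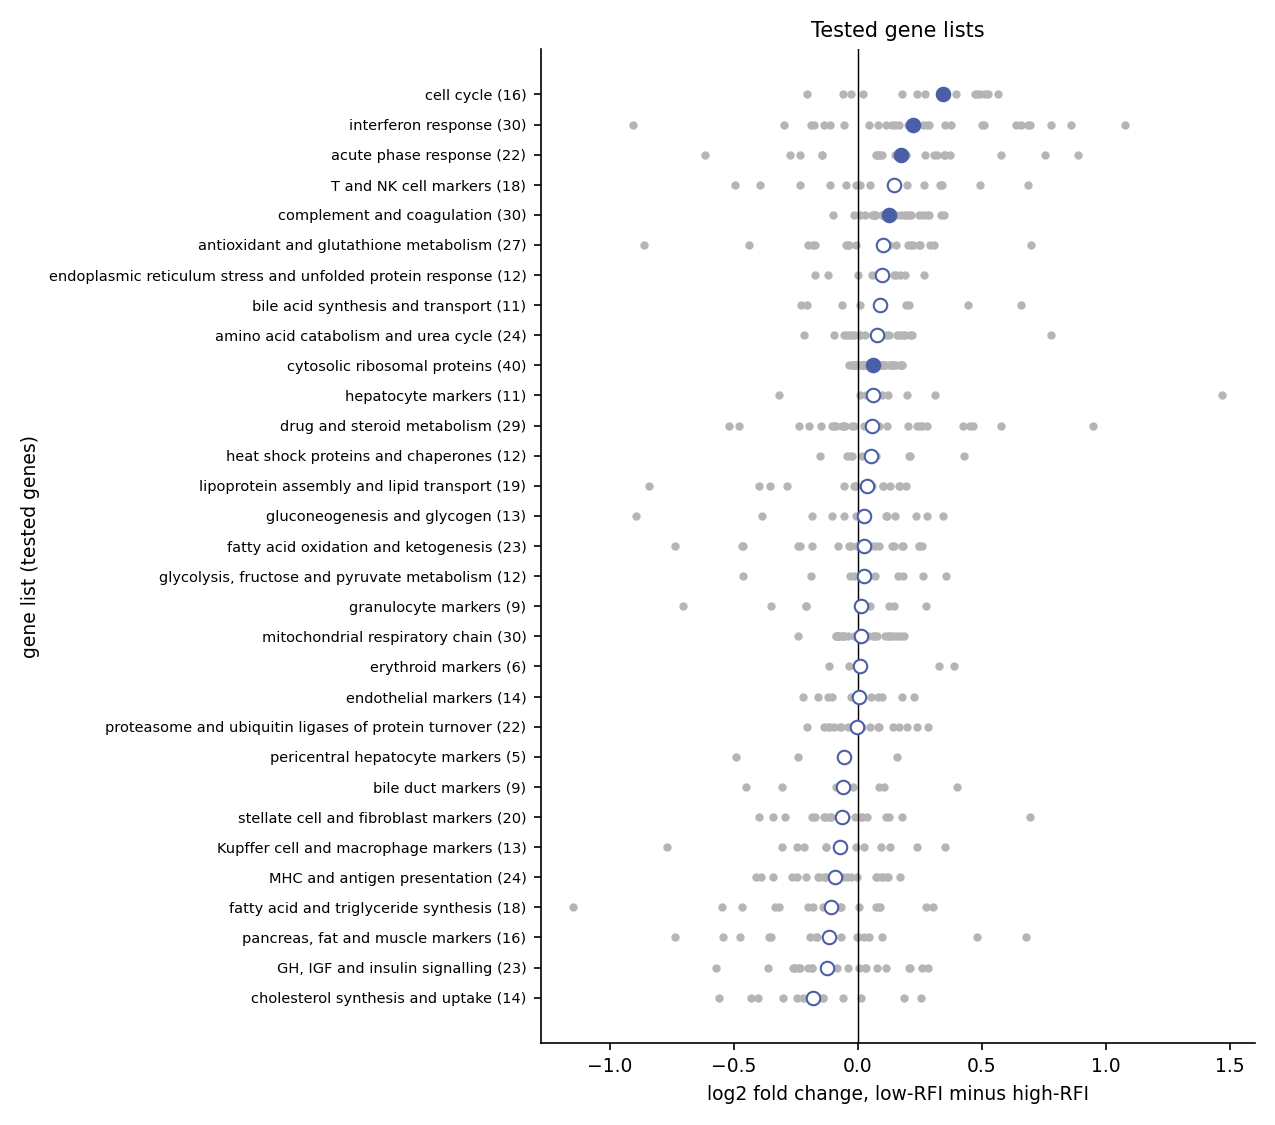
Change of the genes of each tested list (horizontal axis, log2, low-RFI minus high-RFI; small grey dots, genes; large dots, median of the list, filled where the list passed at the preset correlation). The 5 filled medians run from +0.06 to +0.34, and the lowest of them, ribosomal proteins, turned under normexp, and its test turned under quantile normalisation too.

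Cholesterol synthesis and uptake genes had 11 of 14 members lower, with a median of −0.18, and missed the threshold (adjusted p = 0.0508), while they passed under quantile normalisation (0.0287), cyclic loess (0.0297), normexp (0.000235) and the authors' values (0.0387), but not with an estimated correlation (0.974) or by fry (0.972). MHC and antigen presentation genes had 17 of 24 lower, with a median of −0.09 (adjusted p = 0.0821). They passed on the lower side with array noise (0.0174), array position (0.00343), normexp (0.0275), without the marked arrays (0.0476) and within slides 2 (0.00584) and 4 (0.00969), and on the higher side within slide 3 (0.00189), but not with an estimated correlation (0.974). Hepatocyte markers had 10 of 11 higher, with a median of +0.06 that turned under normexp (adjusted p = 0.174), and passed as higher with array weights (0.036), the first principal component (0.0121) and without high-RFI pig 6 (0.0295). Among them the apolipoprotein gene APOM, singled out after its values were seen, was at +0.31 and was the 1 member of any list to pass when adjusted over the list alone, while over all probes tested 0 members of any list passed in limma. Amino acid catabolism and urea cycle genes had a median of +0.08 and their test turned under normexp (adjusted p = 0.174), while they passed as higher without low-RFI pig 4 (0.0471). Growth hormone, IGF and insulin signalling genes were at −0.12 (adjusted p = 0.285) and fatty acid and triglyceride synthesis genes at −0.11 (adjusted p = 0.391), with 14 of 23 and 12 of 18 lower. The latter passed with array noise (0.000485), within slide 3 (0.0164), without the marked arrays (0.0449) and under normexp (0.0324), but not with an estimated correlation (0.981).

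The other metabolic lists also did not pass, though fatty acid oxidation (0.0288), the respiratory chain (0.00211) and the proteasome (0.0288) passed on the lower side under normexp. Antioxidant and glutathione genes were at a median of +0.10 (adjusted p = 0.34) and the endoplasmic reticulum stress list at +0.09 (0.567), and both tests turned under normexp. The latter passed as higher within slide 1 (0.00652) and as lower within slide 2 (0.0476). Heat shock proteins were at +0.05 (0.759), passed as higher within slide 1 (8.94e-05) and also turned under normexp, while bile acid genes were at +0.09 (0.439) under every scaling on the same side. On slide 1 low-RFI pig 2 alone was high for heat shock proteins and endoplasmic reticulum stress, with list means of +1.062 and +1.235 relative to all pigs. Low-RFI pig 7 was at −0.362 and −0.394, high-RFI pig 1 at −0.219 and −0.153, and high-RFI pig 6 at −0.380 and −0.121. Drug and steroid metabolism was at +0.06 (0.668), with a test that turned under normexp, quantile normalisation and cyclic loess. Glycolysis was at +0.02 (0.823), with a test that turned under normexp and quantile normalisation and a median that turned under normexp alone. The respiratory chain was at +0.01 (0.933), its test and median turning under those 2 and cyclic loess, and the test alone under the authors' values. Fatty acid oxidation (median +0.03, mean −0.04, adjusted p = 0.759) and gluconeogenesis (+0.03, mean −0.03, 0.902) had tests on the lower side, and both medians turned under normexp, quantile normalisation and cyclic loess. Lipoprotein genes (+0.04, mean −0.05, 0.933) had a test on the higher side that turned under every scaling but the median. The proteasome list had a median of −0.00 and a mean of +0.02, with its test on the lower side (0.923).

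Markers of other liver cells did not pass either, but some did in single settings. Kupffer cell markers were at a median of −0.07 (adjusted p = 0.567), passing as higher within slide 3 (0.00818) and as lower within slide 4 (0.000396), as interferon response did (7.53e-11 and 9.99e-05). Medians were also negative for stellate cell markers, at −0.06 (0.34, but 0.0447 under normexp and 0.025 within slide 1), bile duct markers at −0.06 (0.567) and pericentral hepatocyte markers at −0.06 (0.336). T and NK cell markers were at +0.15 (0.865), passing as higher under normexp (0.0288) and within slide 3 (5.84e-06) and as lower within slide 4 (9.99e-05), and erythroid markers at +0.01 (0.759). Granulocyte markers had a median of +0.01, a mean of −0.10 and a test on the lower side that turned under normexp (0.823), and passed as lower within slide 3 (0.00189). Endothelial markers had a median and mean of +0.01 and +0.00 with a test on the lower side (0.902), the test turning under normexp and the median under quantile normalisation. Markers of pancreas, fat and muscle were at −0.12 (0.303) and turned under normexp, but passed as lower within slide 1 (1.93e-05) and without high-RFI pig 4 (0.0464). Circadian clock genes and B and plasma cell markers, with 4 measured genes each, and the Y-linked list, with 1, were not tested, at medians of +0.11, −0.06 and −0.03.

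No difference between the lines was detected in the 4 planned measures of array quality. The number of probes well above background was 30050 ± 629 in low-RFI and 30837 ± 2026 in high-RFI arrays (exact permutation p = 0.355, within slides 0.33). For the 75th percentile of signal p was 0.317 (within slides 0.259), for background 0.948 (0.818) and for the median correlation with the other arrays 0.99 (0.991), all by exact permutation. Benjamini-Hochberg values over these 4 were 0.71, 0.71, 0.99 and 0.99. Of measures looked at after the data were seen, the noise of replicated probes kept its difference within slides (exact permutation p = 0.00772). The lowest detectable spike-in was 0.494 in low-RFI and 0.806 in high-RFI arrays, in the scanner software's units (exact permutation p = 0.00979, within slides 0.017). It was highest on the array of high-RFI pig 6 (1.55). That array also had the most probes well above background (35126), the lowest 75th percentile (320) and the lowest median correlation (0.971). The scanner software marked 5 high-RFI and 0 low-RFI arrays for evaluation (Fisher's exact two-sided p = 0.0256). The first principal component held 20.3% of the variance and no difference between the lines was detected on it (exact permutation p = 0.515). The sample numbers in the deposit ran from 1 to 8 and from 55 to 62, each run with 4 pigs of each line and 1 of each line per slide. These 2 series were compared only after other results had been seen, and their meaning is not given. Between them limma called 655 probes and 94 genes, and they differed on the first principal component (exact permutation p = 0.000622). Within the 2 series the changes between the lines were −1.31 and −1.33 for A_72_P302174, −3.78 and −4.98 for A_72_P205617, and −1.43 and −2.16 for A_72_P129381. For the lists the adjusted p within series 1 and 2 was 0.000362 and 0.963 for acute phase, 0.000362 and 0.614 for interferon response and 0.135 and 0.022 for cell cycle. It was 0.0582 and 0.0132 for complement and coagulation and 0.0994 and 0.16 for ribosomal proteins, so no list passed in both.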

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

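The tests of array noise, of the C6orf125 probes and of the series of sample numbers were chosen only after the results were seen. So were the splits with slide and series held even. For the counts over other splits of the pigs, the reading was set down before they were run, but after the main results were known.

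In 6 of 68 groups of 8 pigs, the lowest pig stood apart from its nearest neighbour by a larger share of the group's range than Dixon's limit allows, and chance does so in about 1 of 20 groups. For A_72_P302174, high-RFI pig 4 was at −3.35 and the next at −2.68, a share of 0.583. The same pig was at −4.71 for A_72_P129381, with the next at −3.28, a share of 0.67. High-RFI pig 6 was at −1.18 for A_72_P205617, with the next at 0.87, a share of 0.536, and at −0.25 for F13A1, with the next at 1.37, a share of 0.624. High-RFI pig 5 was at 6.01 for RPL14, with the next at 6.26, a share of 0.617. For MTERFD1, low-RFI pig 1 was at 0.92 and the next at 1.26, a share of 0.594.

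The real split called 3 probes, and only 2 of 100 splits of the 16 pigs, the real one included, called as many. Chance seldom gave this count but is not excluded. The highest other split called 289, which points to a structure among the pigs other than line. These splits did not hold slide or series of sample numbers even, and in 100 of the 128 splits that did, only the real one called 3 or more, the highest other calling 2. A level shift that follows array noise in a straight line is argued against as the whole cause, since 3 of 3 probes kept most of their change with noise as a covariate. The changes were −1.27 (SE 0.218) from −1.32 (SE 0.152) for A_72_P302174, −4.78 (SE 0.817) from −4.38 (SE 0.575) for A_72_P205617 and −1.77 (SE 0.388) from −1.79 (SE 0.27) for A_72_P129381. The calls ended because the SE grew. Noise was higher in high-RFI arrays, so its other effects on these probes cannot be told apart from line. For A_72_P302174 a lower level of the whole transcript is argued against by the other 4 probes of the gene, whose median change was +0.16. With 0 of those 4 probes falling, a sequence variant under this probe or a transcript end that it alone reads may account for its change. Its level was also far below theirs in both lines, so whether it reads this transcript at all is open. For all 3 probes a biological difference between the lines stays among the open explanations, its cause untested.

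The real split called 5 lists, and 81 of 100 splits called as many, with 16 in the highest other split and a median of 8 in the others, so chance cannot be excluded for this count, nor with slide and series held even (77 of 100, highest other 16). For complement and coagulation, 5 of 100 splits gave a p as small as the real 1.43e-06, the smallest other being 1.61e-07, so chance is not excluded there either, nor with slide and series held even (5 of 100, smallest other 1.44e-08). This list had the smallest camera p of the tested lists in the real split, but other splits were counted for it alone. Its count therefore makes the result look rarer than it is. In 2 other splits the smallest camera p of any list was 2.24e-19 and 2.86e-26. Array noise may account for the cell cycle list, whose median went from +0.34 (median SE of its genes 0.253) to −0.15 (0.326) with noise as a covariate, and cannot be told apart from a line difference for the interferon list, whose median went from +0.22 (0.316) to +0.27 (0.452) as its call ended, for a reason that was not tested. The other 3 lists stayed called in the same direction with noise as a covariate. The complement and coagulation median went from +0.13 (median SE 0.127) to +0.20 (0.175). The acute phase median went from +0.17 (0.203) to +0.44 (0.266), and the ribosomal median from +0.06 (0.0868) to +0.10 (0.123). Since other splits gave calls at the preset correlation so often, these calls cannot decide whether noise was the cause. A biological difference between the lines stays open, its cause untested, and no list passed with an estimated correlation.

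For single genes the real split called 0 by limma, with 225 at an unadjusted p under 0.05, so 100 of 100 splits called as many, and the highest other split called 43.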

How the results depend on the processing

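The settings with array position, series of sample numbers, the first principal component or array noise, and the one without the arrays marked for evaluation, were chosen only after the data were seen. The count of 3 probes stayed within 1.5-fold under 18 of 25 settings, though under normexp it was 2, of which 1 was among the 3. A like count did not always mean the same probes. Within slide 2 A_72_P205617 was called beside A_72_P066171 and A_72_P417067, and with no filter A_72_P167661 took the place of A_72_P129381. It was 1 with a filter on all 16 arrays, 7 with array weights, and 0 in limma within slides 1, 3 and 4 (701, 784 and 1017 at an unadjusted p under 0.05), without the marked arrays (1146) and with array noise (1885). With the 5 marked high-RFI arrays left out, the 3 changes were −1.06 (SE 0.204) for A_72_P302174, −4.67 (SE 0.751) for A_72_P205617 and −1.62 (SE 0.423) for A_72_P129381. The count of 5 lists became 9 under normexp, 7 of them lower and 1 shared with the 5, and 0 with an estimated correlation or fry. Normexp moved the median of all probes by +0.09.

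Reversed values were as follows, with adjusted p for lists. The ribosomal list turned under normexp (0.0616), quantile normalisation (0.943) and on slide 3 (0.859). The cell cycle list turned on slide 2 (0.872), with array noise (0.21) and, by its test, without the marked arrays (0.958). On slide 4 acute phase (0.689) and interferon response (9.99e-05) turned. On slide 4 IL1RN was at −0.41, on slides 1 and 3 MASP1 at −0.46 and −0.10, on slide 1 F13A1 at 0.13, and on slide 2 RTN2 at −0.18. Apart from the fewer arrays within a slide, the cause was not tested.

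Leaving out 1 pig gave 2 to 5 probes, 0 to 1 genes and 2 to 7 lists. There were 5 probes without low-RFI pig 2 or high-RFI pig 4. There were 2 lists without low-RFI pig 2 or high-RFI pig 3, and 3 without low-RFI pig 1 or high-RFI pig 1. A_72_P302174 ran from −1.43 to −1.27 and A_72_P205617 from −4.75 to −4.04, called each time. A_72_P129381, at −2.00 to −1.69, was called only without low-RFI pig 2 or 6 or high-RFI pig 4, with adjusted p up to 0.125 without high-RFI pig 5. Complement and coagulation stayed called (adjusted p 4.87e-07 to 0.00126). Acute phase lost its call without low-RFI pig 1 or 2 or high-RFI pig 3 or 4 (up to 0.319), and ribosomal proteins without low-RFI pig 1 or 7 or high-RFI pig 3 or 5 (up to 0.0699). Interferon response lost it without low-RFI pig 2, 5, 6 or 7 or high-RFI pig 1, 3 or 4 (up to 0.425), and cell cycle without low-RFI pig 2, 4 or 6 or high-RFI pig 1 or 2 (up to 0.149).

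Deviations from the line mean correlated at 0.0474 to 0.395 between pigs with the same number, over 0.1 in 6 of 8, so not in every pair, and the numbers were not taken to pair the pigs. As a hint from the data, not the design, 5 low-RFI and 6 high-RFI pigs matched their own number best. Same-numbered pigs share a series of sample numbers, and centred on series 4 of 8 correlations were over 0.1 (−0.00234 to 0.468). With the number as a block 4 probes, 2 of them among the 3, 0 genes by limma (354 at an unadjusted p under 0.05) and 6 lists were called, MHC being added as lower (0.0173). Scan date was the same as slide and was not run apart. Probes near background limit the data: 13506 were too dim to test.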

Other observations

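The relations between lists, the series of sample numbers, the search for probes with on and off levels and all tests of them were chosen only after the data were seen.

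The 2 series of sample numbers, 1 to 8 and 55 to 62, were found by looking at the pigs of the split that called 289 probes, in which 6 of 8 pigs on a side were of 1 series. Between the series themselves 655 probes, 94 genes and 11 lists were called, and their correlation with the first principal component was 0.754. With the series as a block 2 probes passed between the lines, A_72_P129381 missing the threshold (adjusted p = 0.0691, over all alternatives 0.0306 to 1), and 6 lists, cholesterol being added as lower (0.0316; adjusted p = 0.974 with an estimated correlation). The files do not say what the series stand for, and no explanation of them was tested.

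Over the 16 pigs, 465 pairs of list means were compared, and 5 passed by both Pearson's and Spearman's coefficients after Benjamini-Hochberg adjustment. Glycolysis and respiratory chain genes went together most closely (r = 0.917 and rho = 0.906, permutation p = 1e-05 each, the smallest that the permutations can give, adjusted p = 0.00465). Without the 2 pigs farthest from the median r was 0.826, in low-RFI pigs 0.951, in high-RFI pigs 0.898, after centring each slide 0.892, and within the 2 series of sample numbers 0.838 and 0.938. MHC genes went with T and NK cell markers (r = 0.864, permutation p = 5e-05, adjusted 0.00775; rho = 0.815, permutation p = 0.00025, adjusted 0.0251; r without 2 pigs 0.653, slide-centred 0.811, within series 0.725 and 0.899). Fatty acid synthesis genes went with drug and steroid metabolism (r = 0.746, permutation p = 0.00082, adjusted 0.0347; rho = 0.815, permutation p = 0.00027, adjusted 0.0251; r without 2 pigs 0.735, slide-centred 0.642, within series 0.464 and 0.908). Respiratory chain genes went with antioxidant genes (r = 0.817, permutation p = 0.00021, adjusted 0.0244; rho = 0.768, permutation p = 0.00082, adjusted 0.0477; r without 2 pigs 0.646, slide-centred 0.667, within series 0.744 and 0.906). Proteasome genes went with heat shock proteins (r = 0.769, permutation p = 0.00044, adjusted 0.0346; rho = 0.835, permutation p = 2e-04, adjusted 0.0251; r without 2 pigs 0.768, slide-centred 0.821, within series 0.945 and 0.715). In each of these 5 pairs the lists shared 0 genes. The relations were computed under the main scaling only and were not compared with those of random gene lists. A shift shared by many genes of an array was therefore not told apart from a relation particular to these lists.

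In 44 probes the pigs fell apart by a gap of over 1.5 on the log2 scale with at least 4 pigs on each side, where normal values of the same spread would give 13. In none of the 44 did the sides pass a test between the lines after adjustment (smallest adjusted Fisher's exact p = 0.0616), and 6 had an unadjusted p under 0.05. The smallest was for A_72_P205617, with 0 low-RFI and 7 high-RFI pigs above its gap, a probe that limma called (adjusted p = 0.00929). For PON3, a paraoxonase made by liver and carried on HDL, 3 low-RFI and 4 high-RFI pigs lay above gaps of 3.28 to 3.84. For the glutathione S-transferase probes A_72_P302044, A_72_P497485 and A_72_P517950, 6 low-RFI and 4 high-RFI pigs lay above gaps of 10.1, 9.06 and 7.72, which are not exact, since these probes were well above background on only 13, 10 and 15 of 16 arrays. The 4 probes of GSTA1 and GSTA2, well above background on all 16 arrays, showed no such gap. For OAZ3, 2 of 8 low-RFI and 8 of 8 high-RFI pigs lay above the gap (Fisher's exact two-sided p = 0.00699, adjusted 0.103), and its second probe had a gap of 0.558 and a correlation of 0.971 with the first over pigs.

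A sequence variant under a single probe is argued against for PON3, where 3 of 3 probes with no shared stretch divided the same pigs, and for the glutathione S-transferase probes, which read 2 separate stretches that divided the same pigs. Slide is argued against as the whole cause, since pigs of both kinds were found on 4 of 4 slides for PON3 and on 2 of 4 for the glutathione S-transferase probes. The 6 pigs with low glutathione S-transferase signal were all on slides 1 and 3, which leaves a part for slide open there. As a hypothesis, inherited differences between pigs may set these levels, but no genotypes were analysed here.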
